A study of Mus musculus with 6 samples.

How the data were processed

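Gene expression was measured with GeneChip arrays, single-colour Affymetrix arrays on which biotin-labelled DNA made from total RNA binds short probes that are grouped into probe sets. The cells were NMuMG, an epithelial line from mouse mammary gland that responds strongly to transforming growth factor beta (TGF-b). Per the labels' protocols, the cells received a control small interfering RNA (siControl), one against Olig1 (siOlig1) or one against Pin1 (siPin1), and were then left without TGF-b or exposed to it for 1 h. That gives 6 conditions, and each was measured on 1 array.

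The deposited values are on a log scale and were used as log2 values, 1 per probe set and array, as made by the authors. Per the submitters' processing notes, MAS5 and Affymetrix Expression Console were used, with no versions. Which summary method and which normalization gave the deposited log2 values is not given in the sources used here, and the base of the logarithm is not stated either. The reading as log2 rests on the range of the values, from 0.754 to 13.6, so every fold in the text depends on it. The array medians lay between 5.60 and 5.66 over all probe sets. Across the tested genes described below, the arrays correlated between 0.9926 and 0.9979, with 0 pairs holding identical values. For arrays no read depth exists, and the small number of arrays limits the precision.

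The table held 35556 probe sets. The platform annotation named 1 gene for 21789 of them, several genes for 1621 and no gene for 12146. Probe sets with several genes were given no name. Symbols were checked through the gene identifier against RefSeq names of the assembly GRCm38.p6, which held 21698 of the 21789 entries and changed 0 symbols. For the other 91 the symbol of the annotation was kept. The named probe sets covered 19938 genes, and for the 999 genes with more than 1 probe set the one with the highest mean over the 6 arrays was used. Genes with a mean in the top 60% were tested, which left 11963 genes above a level of 5.42 on the log2 scale. Among the 72 named genes, 2 had more than 1 probe set, and these are described where they are named.

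All tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with Benjamini-Hochberg adjustment, threshold 0.05). A single additive model with terms for transfection and for TGF-b was fitted to all 6 arrays. The TGF-b effect is the mean change over 3 pairs of arrays, 1 pair per transfection. The siOlig1 and siPin1 effects are the differences from siControl averaged over 2 pairs of arrays, without and with TGF-b. The model left 2 residual degrees of freedom, to which the variance prior added 4.05, and the median residual SD was 0.0464. With 1 array per condition, the spread behind each p-value is the disagreement between transfections or TGF-b states, which mixes real interaction with noise, and nothing in the labels says that the arrays came from separate cultures. The difference in TGF-b response between transfections has no replicate check, so it is given as values without p-values. For those, the median of a gene set was ranked among 10000 random lists of the same size matched on mean level.

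Gene lists were fixed before the data were examined. They covered TGF-b/Smad early targets, the BMP/Id response, TGF-b pathway components, AP-1 and immediate early genes, epithelial genes, mesenchymal and EMT genes (epithelial to mesenchymal transition), cell motility and adhesion, YAP/TEAD targets, the interferon response, NF-kB and cytokines, G1/S and DNA replication, G2/M and mitosis, p53 targets, unfolded protein and amino acid stress, cholesterol synthesis, hypoxia and glycolysis, the Notch and Wnt response, the Olig and class II bHLH family, prolyl isomerases, ribosomal proteins and housekeeping genes. Markers of oligodendrocytes, myoepithelial and basal cells, fibroblasts and adipocytes, and immune cells stood for other cell types. Of 668 list entries, 48 had no probe set of their own in the annotation. Older symbols matched Gpi1 to Pigq and Loxl2 to Loxl3, which are other genes, so the hypoxia and glycolysis list and the mesenchymal list each held 1 gene not meant for it. The closing section gives the fit without these. Lists were tested with camera at a preset correlation of 0.01 and again with a correlation estimated from the residuals, with adjustment over all lists and the 3 effects, and with fry. The camera test with an estimated correlation rests on the 2 residual degrees of freedom, so a list could hardly pass it after adjustment. The immune list had too few tested members and was not tested.

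The rule for named genes was also fixed before the data were examined. For the TGF-b effect, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold were named. For each knockdown the 10 largest rises and 10 largest falls among the genes past the threshold were named likewise, with the same direction in both TGF-b states. Among the 50 genes with the largest mean rise with TGF-b, the 6 with the most reduced and the 3 with the most increased response under each knockdown were named. Olig1 and Pin1 were to be given in all arrays. Of each described list, up to 4 members with the largest change and any member past the threshold could be named. Predicted genes, clones and receptor families for smell were counted and not named.

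The steps were tested on simulated data with the residual spread of the 11963 genes and 200 changed genes. A 1.3-fold change was recovered in 90.2% of changed genes for the TGF-b effect, 77.4% for siOlig1 and 74% for siPin1, and a 1.5-fold change in 98%, 95.6% and 94.4%. The false calls were 5.49%, 4.49% and 4.45% of the calls. The simulated errors were independent, with no shift of a whole array, no trend of spread with level and no interaction. These rates therefore may not hold for the real arrays. Alternatives to the normalization, the filter, the choice of probe set, the variance model, the blocks and the arrays in the fit were set before the data were examined, and the closing section gives their effect. Figures were drawn with matplotlib 3.10.9.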

Results

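The data are the expression profiles of NMuMG mouse mammary epithelial cells under 3 transfections, siControl, siOlig1 and siPin1, each without and with 1 h of TGF-b. Each of the 6 conditions was measured on 1 array, and 11963 genes were tested. The series asks whether Olig1, a basic helix-loop-helix transcription factor best known from oligodendrocytes, acts as a cofactor of Smad proteins in the motility that TGF-b induces, and it sets the genes affected by the knockdown of Olig1 against those affected by the knockdown of Pin1, a prolyl isomerase. On principal components of the tested genes, the first component held 51.6% of the variance and separated the arrays with TGF-b from those without, and the second held 23.4% and separated the siOlig1 arrays from the others.

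The values of the targeted genes could not check the labels. Olig1 stood at 4.75 (log2) without and 4.82 with TGF-b in the siControl arrays, at 4.86 and 4.93 in the siOlig1 arrays and at 4.80 and 4.91 in the siPin1 arrays. It was thus not lower in the siOlig1 arrays, and it lay below the filter level of 5.42 on every array. No probe set was named for Pin1 alone, so Pin1 was not analysed here. The groups are therefore called by their labels, and each direction given for siOlig1 or siPin1 is that of the arrays so labelled.

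TGF-b raised a set of early response genes within 1 h, by more than the spread between transfections. The largest rise was in Snai1, a transcription factor that represses E-cadherin, which rose 6.16-fold (log2 2.62 ± 0.057 SE over 3 pairs of arrays, limma adjusted p = 2.35e-05). The AP-1 subunits Fos and Junb rose 4.59-fold and 4.04-fold, the small GTPase Rhob 4.44-fold, and Smad7, an inhibitor of the same pathway, 3.36-fold. The stress-inducible genes Gadd45b and Gadd45a rose 3.80-fold and 3.32-fold. Arid3a (3.90-fold), Arid5a (3.28-fold), the forkhead factor Foxq1 (3.50-fold), the ephrin ligand Efna3 (3.28-fold) and the SOCS box gene Spsb1 (3.64-fold) completed the 12 largest rises. Their SE lay between 0.036 for Gadd45b and 0.119 for Spsb1, whose response was 1.68 in siControl, 2.26 in siOlig1 and 1.65 in siPin1 on the log2 scale.

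The largest fall was that of Ppp1r3c, which targets protein phosphatase 1 to glycogen. It was 3.31-fold lower with TGF-b (log2 -1.73 ± 0.044 SE over 3 pairs of arrays, limma adjusted p = 2.53e-05). The chemokines Cxcl1 and Cxcl5 were 3.22-fold and 2.56-fold lower, Myc 2.55-fold lower, and Rnd3, an atypical Rho GTPase, 2.48-fold lower. Txnip, which binds thioredoxin, was 2.44-fold lower and the protease gene Adamts1 2.07-fold lower. The transcription factors Foxa2 and Hhex were 1.97-fold and 1.70-fold lower, Nfkbiz, a nuclear relative of the NF-kB inhibitors, 1.70-fold lower, and Hs3st1 and Zfp763 1.78-fold and 1.83-fold lower. All 24 of these genes moved the same way in each of the 3 transfections, and none lost its call in any alternative that gave it a value.

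**Figure D1:**
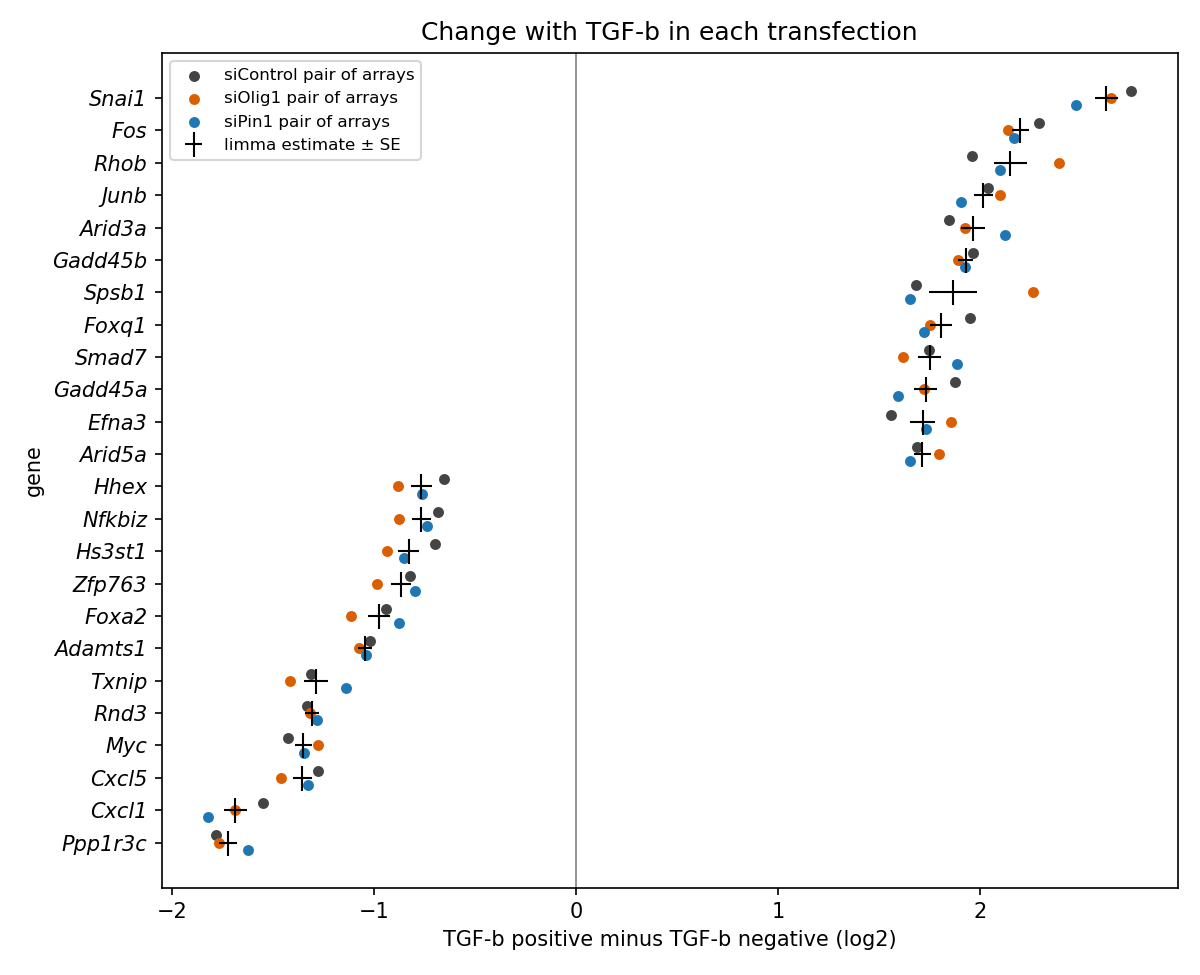
Change with TGF-b (log2, horizontal axis) of the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold. Points are the single pairs of arrays of each transfection, and the black marks are the limma estimate with its SE. Every point lies on the same side of 0 as its estimate, with Snai1 at 2.75, 2.65 and 2.48 in siControl, siOlig1 and siPin1.

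In all, limma called 386 genes higher and 263 lower with TGF-b, of which 130 and 21 changed at least 1.5-fold and 44 and 7 at least 2-fold. The counts rested on which arrays entered the fit and on the model. Without either siPin1 array they were 203 and 65, without either siControl array 143 genes were lower, without transfection as a block 111, with no filter on low genes they were 199 and 57, and with a variance trend 583 and 602.

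Of the 40 measured TGF-b/Smad early targets, 27 rose and 0 fell over all genes, against 33 and 1 adjusted over the list alone (camera adjusted p = 3.22e-36, adjusted p = 0.307 with an estimated correlation). Besides the genes above, the list held the matricellular gene Ccn2 (3.12-fold), the clock-linked repressor Bhlhe40 (3.06-fold), Klf10 (2.63-fold), the inhibitory Smad6 (2.62-fold), and Skil (2.59-fold) and Ski (1.59-fold), which restrain Smad proteins. Of 16 genes of the BMP/Id response, 11 rose over all genes and 12 adjusted over the list alone (adjusted p = 6.36e-16, and adjusted p = 0.357 with an estimated correlation). They included Dlx3 (2.62-fold), Dlx2 (1.72-fold), Hes1 (1.69-fold) and Id1 (1.68-fold). Smad7, Smad6, Id1, Atoh8 and Id3 rose as members of both lists. Hes1 and Hey1 count again in the Notch and Wnt list below, so these lists are not independent. With the estimated correlation no list passed the threshold for any effect. That form of the test uses the 2 residual degrees of freedom. For the TGF-b/Smad early targets the estimate was -0.00737, below the preset 0.01, yet the unadjusted camera p went from 4.47e-38 to 0.00427. For that list the miss therefore does not show that correlation between genes accounts for the shift. Other estimates lay on both sides of the preset, such as -0.0471 for the BMP/Id response and 0.0803 for AP-1 and immediate early genes. They were 0.0715 for G1/S and DNA replication, 0.161 for G2/M and mitosis and 0.0375 for cholesterol synthesis. Where the estimate lay above the preset, correlation between genes may account for part of the miss, and the preset may overstate the shift.

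Of 32 AP-1 and immediate early genes, 20 rose and 3 fell, against 22 and 3 adjusted over the list alone (camera adjusted p = 9.01e-19, adjusted p = 0.357 with an estimated correlation). Fosb rose 2.87-fold, Jun 2.55-fold and Csrnp1 2.13-fold, while Myc, Btg2 and Zfp36 were the members that fell, Btg2 and Zfp36 being 1.38-fold and 1.21-fold lower. The Notch and Wnt list moved up with 7 of 22 genes higher and 1 lower, or 12 and 2 adjusted over the list alone (adjusted p = 1.53e-07, adjusted p = 0.357 with an estimated correlation). Its changed members were the Notch ligands Jag1 (1.85-fold) and Dll1 (1.34-fold), the Notch targets Hes1 and Hey1 (1.56-fold), the Wnt ligands Wnt7b (1.48-fold), Wnt7a (1.32-fold) and Wnt10a (1.17-fold), and Myc, which fell. Of 20 YAP/TEAD targets 8 rose, over all genes and adjusted over the list alone (adjusted p = 2.46e-07, adjusted p = 0.357 with an estimated correlation). Gadd45a, Ccn2, Ccn1 (2.20-fold) and Foxf2 (1.97-fold) carried that shift, since the median of the list was 0.024 against a mean of 0.359 (log2).

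The cell motility and adhesion genes, to which the question of the series points, went both ways. Of 45 measured, 9 rose and 4 fell, against 10 and 6 adjusted over the list alone (camera adjusted p = 0.00339 upwards, adjusted p = 0.473 with an estimated correlation), with a median of 0.014 (log2). Rhob, the growth factor genes Pdgfb (2.59-fold) and Hbegf (1.61-fold), the urokinase gene Plau (1.46-fold) and its receptor Plaur (1.37-fold), the integrin genes Itgb6 (1.43-fold) and Itga5 (1.25-fold), Arhgef18 (1.19-fold) and Lamb3 (1.18-fold) rose. Rnd3, Cdc42ep3 (1.45-fold lower), Mmp13 (1.19-fold lower) and Mmp10 (1.15-fold lower) fell.

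The NF-kB and cytokine genes moved down, with 6 of 22 lower and 2 higher, or 9 and 4 adjusted over the list alone (camera adjusted p = 0.0469, adjusted p = 0.5 with an estimated correlation). Cxcl1, Cxcl5, Nfkbiz, Ccl20 (1.34-fold lower), Tnfaip3 (1.23-fold lower) and Lcn2 (1.17-fold lower) fell, and Ccl7 (1.34-fold) and Csf1 (1.32-fold) rose. Among 25 mesenchymal and EMT genes 3 rose, Snai1, Hmga2 (1.20-fold) and Pdgfrb (1.22-fold), against 6 higher and 2 lower adjusted over the list alone (adjusted p = 0.00125, adjusted p = 0.473 with an estimated correlation). Among 22 epithelial genes Cldn4 (1.57-fold) and Pkp1 (1.21-fold) rose and 0 fell, against 2 and 1 adjusted over the list alone, and the list as a whole did not pass (adjusted p = 0.0849). Of 30 TGF-b pathway components Acvr1 (1.56-fold), Tgfbr1 (1.39-fold) and Tgfb1 (1.16-fold) rose, or 7 adjusted over the list alone (adjusted p = 0.0021, adjusted p = 0.473 with an estimated correlation). Markers of other cell types moved alongside. In the myoepithelial and basal list Krt14, a keratin, rose 1.73-fold as 1 of 6 measured (adjusted p = 0.0373), and in the fibroblast and adipocyte list Pdgfrb rose as 1 of 6, or 4 adjusted over the list alone (adjusted p = 0.00105). For both lists the adjusted p was 0.5 with an estimated correlation.

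In the arrays labelled siOlig1 the largest rise past the threshold was in Alb, serum albumin, which was 2.43-fold higher than in siControl (log2 1.28 ± 0.044 SE over 2 pairs of arrays, 1.26 without and 1.296 with TGF-b, limma adjusted p = 0.00118), and Fgb, the fibrinogen beta chain, was 1.79-fold higher. The glutathione transferase gene Gsta3 rose 2.30-fold, the secreted glycoprotein gene Olfml3 2.07-fold, the nicotinic receptor subunit Chrnb2 1.98-fold, Fbxo36 1.89-fold, and Cd59a, which blocks the complement attack complex, 1.85-fold. Prg4 (1.70-fold), Lipn (1.61-fold) and Cbs (1.56-fold) completed the 10 largest rises past the threshold. The largest fall past the threshold was in Ranbp3l, 2.15-fold lower (log2 -1.10 ± 0.089 SE over 2 pairs of arrays, limma adjusted p = 0.0183), followed by Lgr5, a receptor for R-spondins, 1.75-fold lower, and the adhesion receptor gene Adgrl2, 1.63-fold lower. Slco4a1 was 1.53-fold lower, the oncostatin M receptor gene Osmr 1.48-fold, the activin subunit Inhbb 1.47-fold, the water channel Aqp1 1.46-fold, and the peptidase gene Mme 1.45-fold. Stra6, a retinol transporter, and Dio1, a thyroid hormone deiodinase, were each 1.42-fold lower. For Adgrl2, 7 of 8 probe sets were lower and 1, near background, was 0.09 higher on the log2 scale.

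Altogether 34 genes were higher and 32 lower in the siOlig1 arrays, and 2587 genes had an unadjusted p under 0.05. With array medians equalized the counts became 109 higher and 306 lower, so the share of higher calls moved from 51.5% to 26.3%. That scaling also moved the median siOlig1 effect over all genes from -0.016 to -0.048 (log2). Limma gave 7 higher and 0 lower without the untreated siControl array (852 lower at an unadjusted p under 0.05), 5 and 2 without the treated one, 6 and 0 without either siPin1 array (1249 lower unadjusted) and 89 and 116 without the treated siOlig1 array. With no filter it gave 5 and 0 (1311 lower unadjusted), without TGF-b state as a block 2 and 0 (989 lower unadjusted), with the top 40% of genes 186 and 402, and with a variance trend 321 and 648. Of the 20 named genes, Gsta3 and Olfml3 kept the call in every alternative that was run, and Alb and Chrnb2 lost it in 1, the fit without that block.

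The AP-1 and immediate early genes were higher as a list in the siOlig1 arrays (camera adjusted p = 1.19e-05, adjusted p = 0.496 with an estimated correlation), with a median of 0.145 (log2). Over all genes 1 of 32 passed, Zfp36 (1.43-fold higher), a factor that destabilises mRNA, against 11 adjusted over the list alone. Fosb (0.41 ± 0.105 SE, log2), Fos (0.31 ± 0.053) and Egr1 (0.31 ± 0.053) did not pass over all genes. The cholesterol synthesis genes were lower as a list (adjusted p = 0.000125, adjusted p = 0.473 with an estimated correlation), with 0 of 20 past limma's threshold over all genes, 4 lower adjusted over the list alone, 11 lower at an unadjusted p under 0.05, and a median of -0.122. Their largest changes were in Tm7sf2 (-0.30 ± 0.050) and Cyp51 (-0.22 ± 0.052). The G2/M and mitosis genes (median -0.067, adjusted p = 0.00584) and the G1/S and DNA replication genes (median -0.077, adjusted p = 0.0213) were lower as lists, with 0 of 32 members of either past the threshold by limma, over all genes or adjusted over the list alone, and 7 and 3 lower at an unadjusted p under 0.05. With an estimated correlation these were adjusted p = 0.621 and adjusted p = 0.601. The G1/S shift also missed the threshold after quantile normalization, at adjusted p = 0.0502. In the motility list Mmp13, a collagenase, rose 1.44-fold as 1 of 45, against 7 higher and 5 lower adjusted over the list alone, and the list did not pass (adjusted p = 0.183). The TGF-b/Smad early targets did not shift either (adjusted p = 0.292), with 0 of 40 past limma's threshold over all genes, 1 higher and 1 lower adjusted over the list alone, 6 and 4 at an unadjusted p under 0.05, and a median of -0.005 that became 0.005 after quantile normalization, as the median of all genes moved from -0.016 to -0.005.

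The arrays labelled siPin1 showed higher Tigit, an immune receptor gene, by 1.80-fold (log2 0.85 ± 0.045 SE over 2 pairs of arrays, 0.86 without and 0.84 with TGF-b, limma adjusted p = 0.0146). Anxa10 was 1.70-fold higher, Serpinb5, which encodes maspin, 1.64-fold, Glod5 1.62-fold, and the complement receptor gene C3ar1 1.59-fold. Lncenc1 (1.51-fold), S100a7a (1.495-fold), Ptprn (1.48-fold), the matrix proteoglycan Vcan (1.44-fold) and the stromelysin gene Mmp3 (1.37-fold) followed. Ttr, the thyroxine carrier transthyretin, was 1.76-fold lower (log2 -0.81 ± 0.074 SE over 2 pairs of arrays, limma adjusted p = 0.028), Dio1 1.70-fold lower, Serpina9 1.69-fold, Ranbp3l 1.68-fold, and Acox2, a peroxisomal oxidase of bile acid synthesis, 1.65-fold. Ak4 (1.55-fold lower), the histidine ammonia-lyase Hal (1.54-fold lower), Sptssb and Tfcp2l1 (each 1.52-fold lower) and Alb (1.48-fold lower) completed the 10 largest falls past the threshold. A second, dimmer probe set of Ak4 was at -0.03 (log2).

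In all, 13 genes were higher and 23 lower in the siPin1 arrays, and 1748 had an unadjusted p under 0.05. With array medians equalized there were 37 higher and 148 lower, a share of higher calls of 20% against 36.1%. The median siPin1 effect over all genes moved as well, from -0.013 to -0.028 (log2). By limma 0 genes passed in either direction without any one of the siControl or siPin1 arrays (303 to 656 higher and 597 to 1103 lower at an unadjusted p under 0.05), or with no filter (694 and 1084), or without TGF-b state as a block (279 and 674). Without either siOlig1 array 48 were higher and 137 lower, with the top 40% of genes 46 and 154, and with a variance trend 115 and 289. All 20 named genes therefore lost their call in some of these fits, with no change of direction.

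The cell motility and adhesion genes were higher as a list in the siPin1 arrays (camera adjusted p = 6.36e-06, adjusted p = 0.357 with an estimated correlation), with a median of 0.052 (log2). Mmp3 and the laminin chain gene Lamb3 (1.298-fold) passed over all genes, and 8 of 45 were higher and 1 lower adjusted over the list alone. The integrin gene Itga2 stood at 0.47 ± 0.076 SE (log2) without passing. The hypoxia and glycolysis genes were lower (adjusted p = 2.22e-05, adjusted p = 0.357 with an estimated correlation), with Pdk1, a kinase that restrains pyruvate oxidation, 1.36-fold lower as 1 of 24 over all genes and 6 lower adjusted over the list alone. Bnip3 (-0.53 ± 0.071 SE, log2) and the glycolytic Aldoc (-0.42 ± 0.052) did not pass over all genes. The AP-1 and immediate early genes were higher (adjusted p = 0.000225, adjusted p = 0.5 with an estimated correlation), with 0 of 32 past limma's threshold over all genes, 3 higher and 1 lower adjusted over the list alone, and 8 and 3 at an unadjusted p under 0.05. Cholesterol synthesis was lower (adjusted p = 0.00189) and the TGF-b pathway components were higher (adjusted p = 0.0181), both with 0 members past the threshold by limma over all genes or adjusted over the list alone (6 of 20 lower, and 3 of 30 higher and 1 lower, at an unadjusted p under 0.05), and both at adjusted p = 0.496 with an estimated correlation. The AP-1 and cholesterol synthesis lists moved the same way in the siOlig1 arrays. Each knockdown is set against the same siControl arrays, so an error in those would move a list alike in both. The fixed lists were not tested on the difference between the knockdowns, so these shifts cannot be assigned to either knockdown.

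**Figure D2:**
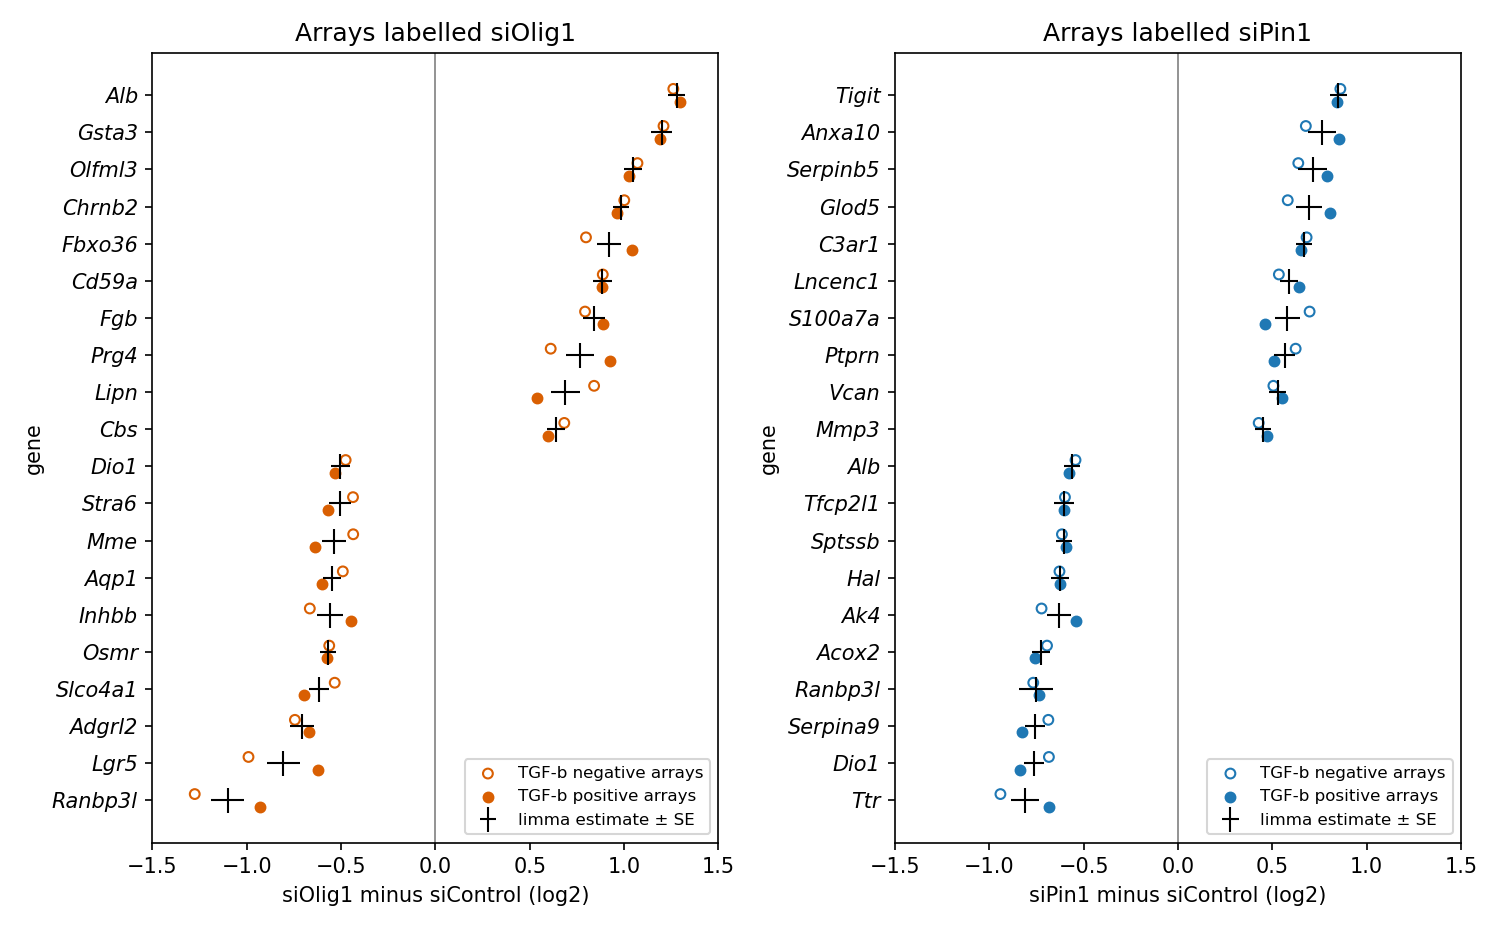
Differences from siControl (log2, horizontal axes) of the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, in the arrays labelled siOlig1 (left) and siPin1 (right). Open points are the arrays without TGF-b, filled points those with it, and black marks the limma estimate with its SE. Alb stands at 1.26 and 1.296 in the siOlig1 panel and at -0.54 and -0.58 in the siPin1 panel.

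The comparison of the knockdowns, which is the one the series names, found 141 genes higher and 70 lower in the siOlig1 than in the siPin1 arrays. The largest named difference was in Alb, 1.84 higher (log2, limma adjusted p = 0.000131), and Gsta3 (1.38), Fgb (1.27), Ttr (1.25) and Acox2 (1.25) also differed, at adjusted p = 0.000982, 0.00129, 0.00331 and 0.000865. Anxa10 (-0.94), Lgr5 (-0.89) and Mmp3 (-0.70) were lower in siOlig1 than in siPin1. With array medians equalized the counts were 221 higher and 199 lower, a share of higher calls of 52.6% against 66.8%. By limma they were 8 and 0 without the untreated siPin1 array (711 lower at an unadjusted p under 0.05), 7 and 0 without the treated one (549 lower unadjusted), and 8 and 0 with no filter (1080 lower unadjusted). Without the untreated and the treated siOlig1 array the lower count was 41 and 110, and the counts were 8 and 2 without TGF-b state as a block, 424 and 458 with the top 40% of genes, and 646 and 699 with a variance trend.

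Few genes were called in both knockdowns. C3ar1 and Tigit were higher in both (2 genes, 0.037 for independent lists), Aqp1, Dio1, Ppp1r3c and Ranbp3l were lower in both (4 genes, 0.062), and Acox2 and Alb were higher in siOlig1 and lower in siPin1 (2 genes, 0.065). Both effects are taken against the same siControl arrays. Simulated unchanged groups gave 0 shared calls of the same direction, but without any effect they leave few calls to share. That simulation therefore cannot show how many shared calls a common control error would give among called genes. The controls are 2 arrays and cannot be split into parts of 2 each, so part of the excess over independent lists may come from the shared controls. Across genes, which are not independent replicates, the effects correlated at 0.0806 when no array was shared, as the mean of -0.0135 and 0.175 over the pairings of states, against 0.00509 in simulated unchanged groups, of which the highest reached 0.0354. With shared siControl arrays the correlation was 0.35 against 0.499 simulated, and the covariance 0.00414 against 0.00254, with a highest simulated covariance of 0.00282. Within a knockdown, the difference from siControl without TGF-b correlated with that under TGF-b at 0.45 for siOlig1 and 0.381 for siPin1.

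Whether the knockdowns altered the response to TGF-b can be described for single arrays only, without a replicate check. At 1.5-fold, 122 genes rose and 31 fell in siControl, 134 and 28 in siOlig1, and 123 and 26 in siPin1, of which 100 rose and 17 fell in all 3. The responses correlated across genes at 0.658 between siControl and siOlig1 and at 0.72 between siControl and siPin1. The 50 genes with the largest mean rise had a median response of 1.31 (log2) in siControl, 1.38 in siOlig1 and 1.29 in siPin1.

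Under siOlig1 the median difference in response of these 50 genes was 0.081 (log2, SD 0.218 over genes), which ranked at the 99.9th percentile of random lists, with 21 genes reduced and 29 increased. Among the reduced were Fosb, with 1.25 in siOlig1 against 1.70 in siControl, Ccn1 (1.04 against 1.27), Foxq1 (1.75 against 1.95), Gadd45a (1.72 against 1.88), Fos (2.14 against 2.29) and Fosl2 (0.93 against 1.08). Of these, all but Gadd45a stood higher in siOlig1 than in siControl with TGF-b, and by more without it. Fosb was at 7.56 against 7.374 with TGF-b and at 6.309 against 5.674 without. Gadd45a was lower with TGF-b, at 8.777 against 8.878. Spsb1 (2.26 against 1.68), Lmcd1 (1.36 against 0.82) and Nfatc2 (1.304 against 0.77) had the most increased response. For 50 genes chosen in the siPin1 pair alone, the choice that uses none of the arrays compared, it was 0.0409, at the 83.3rd percentile. With array medians equalized it was 0.148, but the median of all genes moved alike, from 0.017 to 0.084. Under siPin1 the median difference was -0.022 (SD 0.152), at the 5.5th percentile, with 26 reduced and 24 increased, and with array medians equalized it was 0.0198, below the median of all genes as before (0.046, and 0.004 in the main analysis). Klf10 (1.25 against 1.53), Gadd45a (1.59 against 1.88), Snai1 (2.48 against 2.75), Csrnp1 (0.94 against 1.20), Foxq1 (1.72 against 1.95) and Pdgfb (1.25 against 1.47) had the most reduced response, and Arid3a (2.12 against 1.84), Nuak1 (1.23 against 0.99) and Smad6 (1.48 against 1.28) the most increased. All of those reduced except Gadd45a stood higher in siPin1 than in siControl without TGF-b. With TGF-b they were lower, Snai1 by only -0.002. For neither knockdown did the response of any of the 50 genes differ from that in siControl by 1.5-fold or more.

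Of the lists, the 45 motility and adhesion genes had a median difference in response of -0.016 (log2, SD 0.121 over genes) under siOlig1, with 24 reduced and 21 increased, at the 0.2nd percentile of random lists, whose median was 0.03. That sign turned with array medians equalized, to 0.05, as the median of all genes moved from 0.017 to 0.084. After quantile normalization the difference was -0.04, with all genes at -0.006, so under each scaling it lay below the median of all genes. Under siPin1 it was 0.005 (20 reduced and 25 increased), at the 32.6th percentile, and -0.015 after quantile normalization, as the median of all genes moved from 0.004 to -0.009. The 40 TGF-b/Smad early targets had a median difference of 0.01 under siOlig1, at the 27.8th percentile, and of 0.003 under siPin1, at the 40.1st percentile. After quantile normalization they were -0.02 and -0.004, as the medians of all genes moved from 0.017 to -0.006 and from 0.004 to -0.009. The 32 AP-1 and immediate early genes were at 0.029 under siOlig1 (69.5th percentile) and at -0.043 under siPin1 (3rd percentile), and the 16 BMP/Id genes at 0.016 and 0.032 (62nd and 85.2nd percentile).

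**Figure D3:**
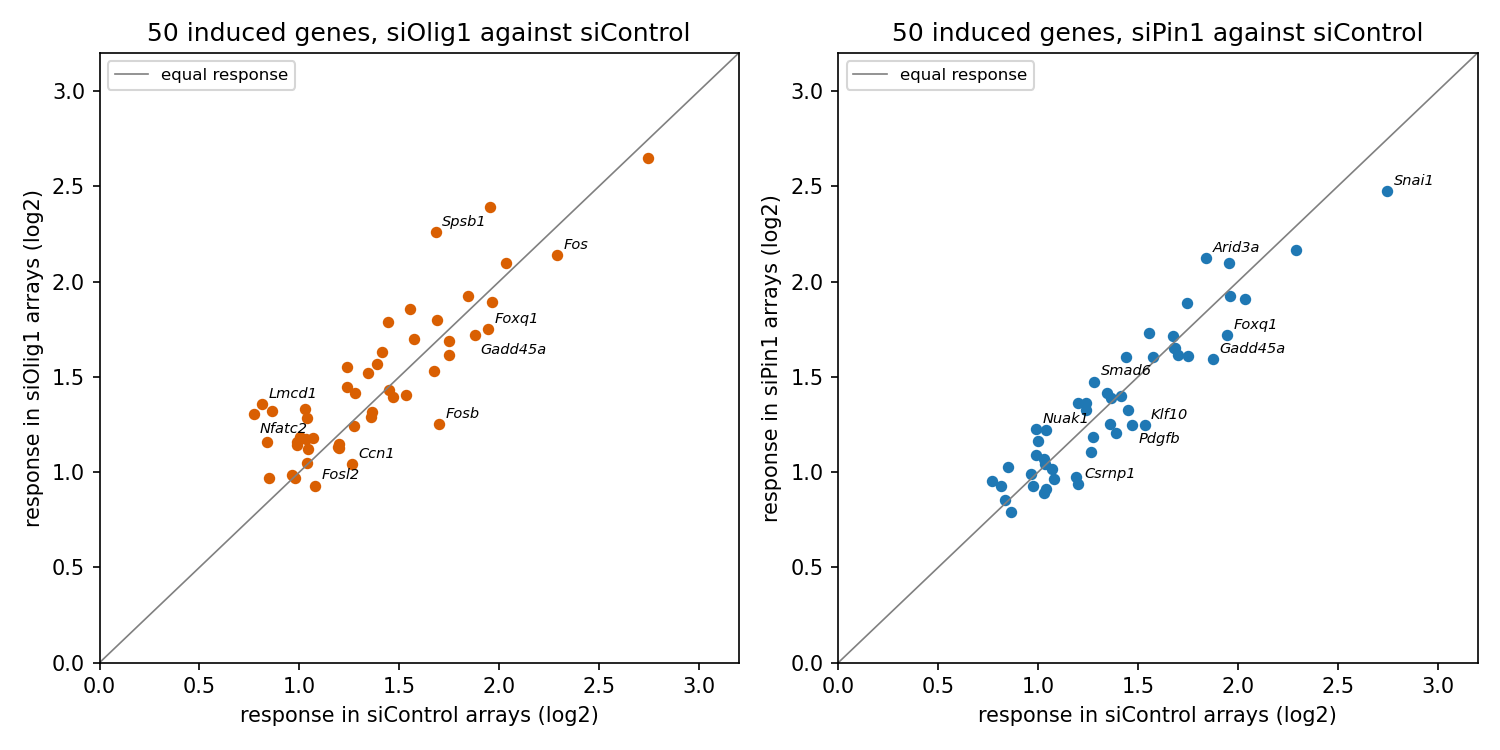
Response to TGF-b (log2, 1 pair of arrays each) of the 50 genes with the largest mean rise, in siControl (horizontal axis) against siOlig1 (left panel) and siPin1 (right panel). The line marks equal response, with 21 genes below it for siOlig1 and 26 for siPin1.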

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

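The tests of explanations here were set before their own results were seen, although the patterns had been seen, and the restriction to liver transcripts above the filter level was chosen after the result was seen, as were the plasma protein part of the liver-type list and the single genes named from it.

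Alb and Acox2 were higher under siOlig1 and lower under siPin1, with a difference between the knockdowns of 1.84 and 1.248 (log2), each past the threshold by limma's test of that difference (adjusted p = 0.000131 and 0.000865). For RNA from liver in the siOlig1 arrays, the prediction was that its other abundant transcripts rose with Alb, by about 1.28. The 14 on the array had a median change of 0.0663 with an SD of 0.172. The 6 above the filter level had a median of 0.157 with an SD of 0.219 and a highest value of 0.538. These values lay below the prediction, but it did not allow for each transcript's own level in the cells. The 14 also left out Fgb, which rose in the siOlig1 arrays, but held the fibrinogen genes Fga (0.066) and Fgg (0.099). Both lay below the filter level, at 4.68 and 3.55. Above it Apoa1 (-0.036), Apoa2 (-0.001) and Trf (0.063) hardly changed, while Hp (0.25), Ambp (0.294) and Hpx (0.538) rose. With values on both sides, the test cannot exclude that source. RNA from liver stays open, and so does a shift of plasma protein genes as a group, with more of them in the siOlig1 than in the siPin1 arrays. The 6 transcripts above the filter level belong to that group too. Of 88 listed liver-type genes not named before, 21 were measured with a median difference of 0.0892 (camera unadjusted p = 9.17e-06, p = 0.0398 with an estimated correlation). The 16 plasma protein genes among them had a median of 0.0955, with 14 above 0 (camera unadjusted p = 4.43e-05, p = 0.0536 with an estimated correlation). Of these 16, Hpx, Hp, Ambp, Itih2 and Agt passed limma's threshold over all genes.

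Olig1 was not lower in the arrays labelled siOlig1, where it was 0.115 (log2) higher than in siControl. Its mean of 4.85 lay at the 93.7th percentile of 1027 olfactory receptor genes, whose central range reached from 2.03 to 4.95, so a probe set at background is a candidate explanation. An exchange of labels between treated arrays would have lowered the residual sum of squares of the additive model, and every such exchange raised it, the least by a factor of 1.61. A wrong label on both arrays of a transfection stays open, and so does a knockdown that these values cannot show.

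The differences in TGF-b response from siControl correlated across genes at 0.597 between the knockdowns, against 0.497 from shared controls in simulated data, of which the highest was 0.549. Removing a trend on mean level left 0.581, which argues against that trend as the whole cause. The covariance of 0.0118 lay within the simulated range, whose mean was 0.00996 and whose highest value was 0.0124, so the shared siControl arrays may account for the pattern, and no shared effect was established. A change in the response that both knockdowns share stays open and untested.

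Among probe sets without a gene name, 93 of 5605 above the filter level changed with TGF-b in a limma fit with the named genes, 23 higher and 70 lower, while 0 passed in a limma fit without them, where 569 had an unadjusted p under 0.05. Probe set 10534667 was 5.71-fold higher (2.81, 2.33 and 2.40 in siControl, siOlig1 and siPin1, log2), 10427877 was 2.15-fold higher, and 10344006 and 10342533 were 2.25-fold and 2.01-fold lower.

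For the TGF-b effect, 1 of the 10 splits of the 6 arrays into groups of 3, with transfection kept as a block, gave as many as 649 genes, the real one, and the highest of the others was 0 by limma, while at an unadjusted p under 0.05 the real one gave 2434 and the 3 others that also part every pair at most 371. The other 6 splits rest on 1 pair each under that block, so they are not fits of the same form. The 10 are too few for a share under 0.05.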

How the results depend on the processing

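Of the alternatives to the main analysis, the removal of an intensity trend and that of 2 list members were chosen after seeing the data. All 24 named TGF-b genes kept their call under every alternative that gave them a value. None of the genes with the largest changes, 24 for TGF-b and 20 for each knockdown, changed direction. The further list members named above were not followed through the alternatives. The fall of spread with level was left out of the main fit. Limma's counts of higher and lower genes moved most for the knockdowns, and the cause was not tested except where fewer arrays or more dim genes enter by construction. With array medians equalized they were 109 and 306 for siOlig1, 37 and 148 for siPin1, and 221 and 199 for siOlig1 minus siPin1, and the induced genes' response difference under siOlig1 was 0.148, where the median of all genes moved from 0.017 to 0.084. That difference was 0.0409 against 0.0812 with the set chosen in the siPin1 pair, at the 83.3rd instead of the 99.9th percentile. With no filter they were 199 and 57 for TGF-b, 5 and 0 (1311 lower at an unadjusted p under 0.05) for siOlig1, 0 and 0 (694 and 1084) for siPin1, and 8 and 0 (1080 lower) for the difference. With the top 40% of genes they were, for siOlig1, siPin1 and the difference in this order here and below, 186 and 402, 46 and 154, and 424 and 458. With a variance trend they were 583 and 602 for TGF-b, 321 and 648, 115 and 289, and 646 and 699. Robust variance gave 15 lower for siPin1. Without transfection as a block 111 were lower with TGF-b. Without TGF-b state as a block the counts were 2 and 0 (989 lower unadjusted), 0 and 0 (279 and 674), and 8 and 2. The siControl and siOlig1 arrays alone gave 6 and 0 (1249 lower unadjusted), and the siControl and siPin1 arrays alone 48 and 137. Leaving out 1 array or pair gave 203 to 438 higher and 65 to 330 lower for TGF-b, 5 to 89 and 0 to 116 for siOlig1, 0 to 48 and 0 to 137 for siPin1, and 7 to 156 and 0 to 110 for the difference. A lone array of a transfection was then taken to vary like the others.

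For single pairs, no filter gave 191 higher and 58 lower in siControl and 54 and 48 lower in siOlig1 and siPin1, the top 40% gave 12, 16 and 15 lower, and a 2-fold limit 43 and 8, 49 and 9, and 41 and 7. The correlation of the knockdown effects was 0.35 with shared siControl arrays. Of the list shifts past the threshold, 11 for TGF-b, 4 for siOlig1 and 5 for siPin1, none passed with an estimated correlation. By fry 2, 3 and 2 of them missed it, and 2, 1 and 1 others passed: hypoxia and glycolysis (adjusted p = 0.0319, higher) and housekeeping (0.0383, lower) with TGF-b, housekeeping under siOlig1 (0.0383, lower), and NF-kB and cytokines under siPin1 (0.0299, lower). Leaving out Pigq and Loxl3 changed no list call by camera. Alternatives to a pseudocount were not run, as the values were on a log scale. The arrays were paired only by shared transfection or TGF-b state, as the labels carry no replicate numbers. Dim genes limit the calls, and Olig1 lay below the filter level.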

Other observations

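Several lists did not shift as a whole with TGF-b by camera but held members that changed by limma. Among 24 p53 targets 3 rose and 3 fell, or 5 and 5 adjusted over the list alone (camera adjusted p = 0.558): Gadd45a, the mTOR inhibitor gene Ddit4 (2.10-fold) and Mdm2 (1.296-fold) rose, and Btg2, Sesn2 (1.21-fold lower) and the proapoptotic Bbc3 (1.19-fold lower) fell. Among 24 hypoxia and glycolysis genes 4 rose and 1 fell, or 4 and 4 adjusted over the list alone (camera adjusted p = 0.861, while fry passed upwards at adjusted p = 0.0319 with a list median of -0.036). The growth factor gene Vegfa rose 2.06-fold, the hexokinase gene Hk2 1.63-fold and Pfkfb3 1.504-fold, besides Ddit4, while Bnip3 was 1.23-fold lower. Among 28 unfolded protein and amino acid stress genes 5 rose and 3 fell, over all genes and adjusted over the list alone (adjusted p = 0.601), with Atf3 (1.51-fold) and Cebpb (1.43-fold) higher and Ddit3 (1.44-fold lower) and Dnajb9 (1.27-fold lower) lower. E2f2 was 1.28-fold lower as 1 of 32 G1/S and DNA replication genes, 0 higher and 1 lower adjusted over the list alone (adjusted p = 0.989), Irf9 1.21-fold lower as 1 of 18 interferon response genes, 1 and 2 adjusted over the list alone (adjusted p = 0.594), and Mbp 1.14-fold higher as 1 of 4 oligodendrocyte markers, 1 and 0 adjusted over the list alone (adjusted p = 0.102).

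For the other lists tested limma called 0 members with TGF-b, over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 2 of 32 G2/M and mitosis genes and 2 of 19 prolyl isomerases were lower, and of 20 cholesterol synthesis genes 1 was higher and 4 lower, against 0 in the Olig family, ribosomal and housekeeping lists. The immune list, too small for camera, had 2 measured members, Cd14 and Cd68, of which limma called 0 over all genes and both were lower with TGF-b adjusted over the list alone (-0.163 and -0.107 log2, adjusted p = 0.0166 and 0.0227, against 0.0961 and 0.164 over all genes). Cd68 was higher adjusted over the list alone under siOlig1 (0.151, adjusted p = 0.0258) and siPin1 (0.217, adjusted p = 0.00467), against adjusted p = 0.143 and 0.124 over all genes. The camera adjusted p was 0.265 for G2/M and mitosis, 0.124 for cholesterol synthesis, 0.861 for the Olig and class II bHLH family, 0.201 for prolyl isomerases, 0.565 for ribosomal proteins and 0.568 for housekeeping genes, which fry placed lower at adjusted p = 0.0383. Among the lists not described for these effects, the adjusted p lay between 0.119 and 0.991 for siOlig1 and between 0.0818 and 0.991 for siPin1.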
